A study of Homo sapiens with 6 samples.

How the data were processed

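RNA-seq was done on cells labelled HepG2 treated for 4 h with DMSO or saikosaponin A at 20 µM, with 3 libraries per group. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads and fragmented, and strand-marking dUTP libraries were amplified by PCR after bead size selection. Poly(A) selection under-represents transcripts that lack a tail, such as replication-dependent histone mRNAs and mature tRNAs, and the loss of long transcripts from broken RNA can move fold changes with length. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and the build GRCh38 were used; their settings, the annotation release, the strand setting and the step that turned alignments into counts are not given in the sources used here.

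The deposited table held 29435 rows by Ensembl gene ID with coordinates, a whole-number count and an FPKM value per library, per the file headers, and annotation terms of GO, KEGG and Reactome. The counts were taken as not normalised by the authors. Their totals differed between libraries, from 57768359 to 74912492, which goes against scaling to a common total but not against other scalings. The deposited FPKM values had been divided by gene length and library size by the authors, per the file headers, and were used for the expression filter, for levels of marker genes and for alternatives. Columns marked SA were read as saikosaponin A and unmarked columns as DMSO, with the number in the name as the replicate. Gene IDs were matched to GENCODE 29 for transcript length and GC content: 28679 rows matched, and 28649 of these overlapped on the same chromosome. A gene's length was that of its longest GENCODE 29 transcript, which need not be the one expressed; 99.6% of tested rows had one.

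Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested (11427 rows). Counts were scaled by TMM and tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. Group means of CPM (counts relative to the TMM-scaled library size) are given with the SD over 3 libraries. The biological coefficient of variation was 15.3%. The design foresaw limma on FPKM or, if counts were held, edgeR, so edgeR was the main test and limma on log2(FPKM + 1) an alternative. For the same reason camera ran on log2 CPM with a prior count of 2.

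Before the data were examined, 33 gene lists of 814 different genes, the tests, most alternatives and the rule for named genes were fixed. Of these genes 743 had a row and the other 71 were not analysed here. Lists with at least 5 tested members (28 of 33) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists. With the correlation estimated for each list, 0 of the 10 calls held. Terms with 10 to 500 tested genes were tested with a one-sided Fisher's exact test for higher and for lower genes, adjusted over both directions (8522 tests), against the tested genes annotated in the same source. For a property such as length, genes are not independent replicates.

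Named genes were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean FPKM was at least 2 in the higher group, up to 4 members of smallest p per called list and 2 per other list, 2 per enriched term named, and a fixed set of stress, ferroptosis and cholesterol genes. Rows named after a sequencing clone were read as having no gene symbol; this reading was chosen after the data were seen and passed over 6 rows. Overlap with another gene on the same strand is given in the text for TEN1, SRCAP and LTB4R2. Other named genes, among them C3, ACSL4, HSPA8, DDIT3, VTN, COX6A1 and MT-TY, also overlap a gene on their strand, and their values carry the same uncertainty.

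On counts simulated for this comparison from the real means and library sizes over 11427 genes, edgeR recovered 40.3% of 67 genes changed 1.5-fold, 85.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 8.02% of its calls were false. With a simulated length trend, 95.9% of the calls were false without the length correction and 5.37% with it. That trend was linear in the same log2 length that the correction uses, and far fewer genes were changed than were called in the data. The simulation therefore shows that the correction runs as written, not how well it acts on the real trend. The camera and term tests found the list and the term raised in the simulation and called 0 of 27 unchanged lists. Genes were drawn independently there, whereas the estimated correlation in the data was 0.77 for the ribosomal protein list. The simulation therefore does not show how camera behaves with correlated members. With the real libraries regrouped into other splits of 3 and 3, camera called 3 to 8 lists although 0 genes passed by edgeR. Each of those splits mixes the treatments unequally, so part of the treatment difference stays between its sides. They are therefore not data without change, and those calls need not be false.

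Replicates were compared before averaging: the closest pairs, DMSO replicates 1 and 2 and saikosaponin A replicates 2 and 3, differed by a chi-square of 15.6 and 15.3 per gene. The other pairs within a group differed by 332 to 433. Each library counted as 1 sample. Alternatives were DESeq2, other scalings, filters and pseudocounts, limma on FPKM, library weights, a replicate block, leaving out each library, and other list tests. Added after seeing the data were a correction of each library's log2 CPM for transcript length by loess, the same with GC content, a term for the 2 libraries of high mitochondrial share, a fit to the other 4, and a fit without mitochondrial rows. TMM factors on FPKM were not computed, since counts were held. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.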

Results

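RNA was sequenced from cells labelled HepG2, a line derived from a human liver tumour, after 4 h with saikosaponin A at 20 µM or with its vehicle, DMSO. Saikosaponin A is a triterpenoid saponin of Bupleurum root. There were 6 libraries, 3 per group. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples. The total counts were 72162625, 74912492 and 57768359 for DMSO replicates 1, 2 and 3, and 58955482, 69567633 and 64666078 for saikosaponin A replicates 1, 2 and 3. The design implies 1 comparison, saikosaponin A against DMSO, which asks which transcripts differ after 4 h of treatment.

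Hepatocyte transcripts were near the detection floor in all 6 libraries. Of the 15 genes with a row among those for proteins secreted by hepatocytes, 12 had a mean below 0.1 FPKM, including the apolipoprotein gene APOA1, transferrin (TF) and the fibrinogen genes FGA, FGB and FGG. These 12 genes together gave between 9 and 39 counts per library, or 0.156 to 0.521 CPM, here counts relative to all counts of the library (group means of single genes below use TMM-scaled library sizes). The highest of the exact 95% Poisson limits was 0.712 CPM, for DMSO replicate 2. Such limits cover counting error only and hold if the deposited counts are numbers of reads, which is not given in the sources used here. The hepatocyte transcription factor gene HNF4A had at most 8 counts in any library, and 13 of 21 genes of the list of hepatocyte transcription factors and metabolism were below 0.1 FPKM. The liver transporter gene ABCC2 was well detected, at 178 ± 0.687 CPM in DMSO and 144 ± 4.82 with saikosaponin A (SD, n = 3). VTN rose by 0.71 ± 0.12 on the log2 scale (SE, edgeR adjusted p = 0.00289), and C3 fell by 0.57 ± 0.18 (edgeR adjusted p = 0.0345), a call that was lost without DMSO replicate 1 (edgeR adjusted p = 0.0719), without DMSO replicate 3 (0.0883), without saikosaponin A replicate 2 (0.102) and without saikosaponin A replicate 3 (0.102). Albumin (ALB) and alpha-fetoprotein (AFP) were not analysed here. Of the markers of other cell types, 7 of 15 fibroblast and stellate cell genes, 2 of 10 endothelial genes, 1 of 5 leukocyte genes and 3 of 12 genes of keratinocytes and other epithelial lines had a mean of at least 1 FPKM.

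By Pearson correlation libraries resembled each other most within a group. Pearson correlations of log2(FPKM + 1) across the 11427 tested genes, which are not independent replicates, were 0.979 to 0.995 within groups and 0.926 to 0.960 between them. By chi-square per gene, saikosaponin A replicate 1 was closer to DMSO replicate 3 (372) than to saikosaponin A replicates 2 (433) and 3 (380). The first principal component held 65.9% of the variance and separated the groups. The second, with 17.9%, set DMSO replicate 3 and saikosaponin A replicate 1 apart from the other 4 libraries. In those 2 libraries the mitochondrially encoded genes took 14.9% and 18.8% of the counts, against 6.19 to 8.28% in the other 4. Across the tested genes, log2 fold changes between those 2 libraries and in the fit to the other 4 had a Spearman correlation of 0.89.

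Among genes above the FPKM limit set for named genes, immediate early transcription factor genes rose most after saikosaponin A, and many long transcripts, among them that of the histone methyltransferase gene KMT2D, were lower than in DMSO. FOSB rose 39.8-fold, EGR1 22.4-fold, FOS 18.2-fold and JUN 12.7-fold. KMT2D fell 9.48-fold, from 202 ± 38.3 to 21.3 ± 0.715 CPM (SD, n = 3). Of 11427 genes tested, 6146 changed, 2956 upward and 3190 downward, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. At least 2-fold changes were fewer, at 229 higher and 619 lower. The groups did not overlap in 62.8% of genes, where chance gives 10%. On the scale of deposited FPKM with limma, 914 genes were higher and 3723 lower, with a median log2 fold change of -0.11. On the TPM scale 49 were higher and 2446 lower, around a median of -0.31, so the changes here are relative to the TMM scaling of the counts.

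The largest rises by rule were in genes of the early response to growth factors and stress. FOSB (chromosome 19, 45467995 to 45475179, GRCh38) went from 1.12 ± 0.140 to 44.9 ± 10.98 CPM (SD, n = 3; log2 fold change 5.31 ± 0.23 SE, edgeR adjusted p = 3.94e-05). EGR1 (chromosome 5, 138465479 to 138469303) went from 1.84 ± 0.752 to 40.6 ± 15.9, and FOS (chromosome 14, 75278826 to 75282230) from 4.37 ± 0.568 to 79.4 ± 14.4. JUN (chromosome 1, 58780791 to 58784047) went from 4.59 ± 0.398 to 57.99 ± 12.999. ATF3, a stress-induced transcription factor gene, rose 8.01-fold, and the chemokine gene CXCL2 rose 9.01-fold from a low level of 0.405 ± 0.0521 CPM. The chemokine gene CXCL8 lay under the level set for named genes and was picked after its values were seen; its log2 fold change was 5.63 ± 0.65 (SE, edgeR adjusted p = 6.03e-04). Among the 29 tested immediate early and AP-1 genes, 18 rose and 1 fell, the same counts as when adjusted over the list alone. ZFP36 (1.83 ± 0.34), DUSP5 (1.38 ± 0.19) and NR4A1 (1.16 ± 0.17) were further rises on the log2 scale (SE), named after their values were seen, and FOSL2 was the gene that fell (-0.98 ± 0.10). The list's camera test gave adjusted p = 2.66e-05 and its median was 0.67; adjusted p = 0.44 with an estimated correlation. After a correction for transcript length, added after seeing the data, its median was 0.54 and its camera adjusted p = 1.1e-04.

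**Figure D1:**
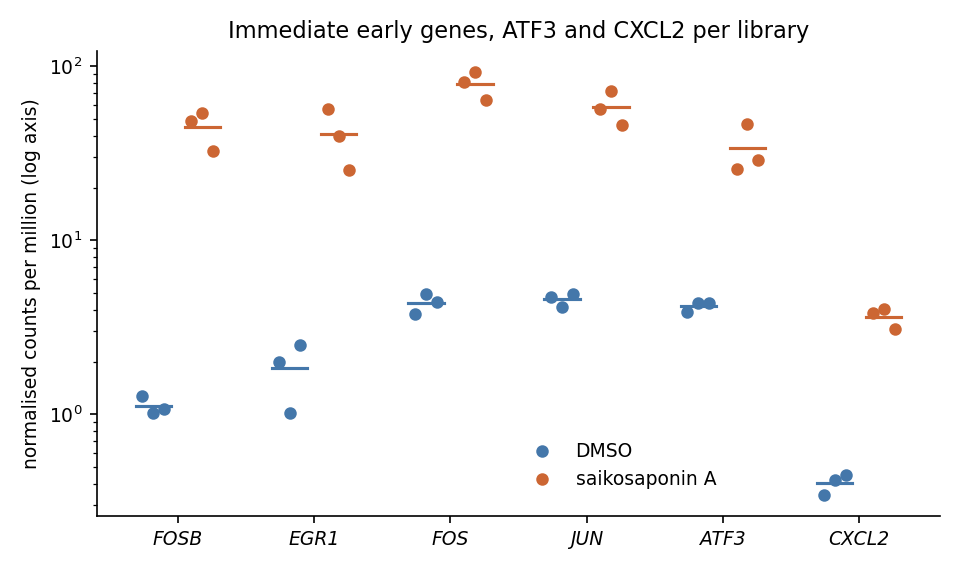
Normalised CPM (log axis) of FOSB, EGR1, FOS, JUN, ATF3 and CXCL2 in each library. Points are libraries (3 per group), and lines are group means. FOSB had a mean of 1.12 in DMSO and 44.9 with saikosaponin A, and in each of the 6 genes the 3 saikosaponin A libraries lay above the 3 DMSO libraries.

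BEST1 and TEN1 were also among the 8 largest rises, with less certain values. BEST1 (11.5-fold, edgeR adjusted p = 0.0259) varied widely in DMSO, at 21.0 ± 27.95 CPM (SD, n = 3), and BEST1 lies on the opposite strand of the abundant ferritin gene FTH1. Its values in DMSO replicates 1, 2 and 3 were 3.90, 5.84 and 53.3 CPM, so replicate 3 largely sets the size of the fold. Its call was lost without DMSO replicate 1 (edgeR adjusted p = 0.0517), without DMSO replicate 2 (0.0611), without saikosaponin A replicate 2 (0.0665) and without saikosaponin A replicate 3 (0.0665). TEN1 (10.8-fold) overlaps the readthrough gene TEN1-CDK3 on the same strand, and how the counting divided such reads is not given in the sources used here.

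Genes of the integrated stress response, which ATF4 drives when eIF2 is phosphorylated, rose as a group. Of 36 tested, 23 rose and 4 fell, the same counts as when adjusted over the list alone, with a median log2 fold change of 0.35. ATF4 itself rose from 205 ± 3.82 to 335 ± 3.42 CPM (SD, n = 3; log2 fold change 0.71 ± 0.05 SE, edgeR adjusted p = 1.48e-04), and NUPR1 rose by 0.77 ± 0.08. DDIT3, which encodes the transcription factor CHOP, rose by 1.002 on the log2 scale (edgeR adjusted p = 0.0103). The cystine transporter gene SLC7A11, another ATF4 target, fell by 0.79 ± 0.09 on the log2 scale. The camera adjusted p was 8.6e-04 for the list; adjusted p = 0.44 with an estimated correlation. On the TPM scale the list's median was -0.02. With the length correction the median was 0.24 and the list's camera adjusted p = 0.0012, while DDIT3 (log2 fold change 0.54 ± 0.19, edgeR adjusted p = 0.0709) and SLC7A11 (-0.10 ± 0.09, edgeR adjusted p = 0.448) no longer passed.

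Chaperone genes of the endoplasmic reticulum and of the cytosol rose by smaller amounts. Of 27 tested genes of the ER chaperone and ATF6/XBP1 list, 16 rose and 3 fell, the same as when adjusted over the list alone (median 0.29, camera adjusted p = 0.0116; adjusted p = 0.44 with an estimated correlation); on the TPM scale its median was -0.07 and on the scale of deposited FPKM its call was lost (camera adjusted p = 0.0594). MANF rose by 0.76 ± 0.07 on the log2 scale, XBP1 by 0.55 ± 0.07, CALR by 0.49 ± 0.07, PDIA3 by 0.47 ± 0.05 and HSPA5 by 0.40 ± 0.07 (SE; edgeR adjusted p from 3.25e-04 for MANF to 0.00289 for HSPA5). With quantile-normalised FPKM, CALR and HSPA5 had log2 fold changes of -0.06 and -0.09. In the heat shock list, 14 of 18 rose and 0 fell, also when adjusted over the list alone (median 0.51, camera adjusted p = 2.66e-05; adjusted p = 0.44 with an estimated correlation), and its median stayed above 0 under each scaling, although the call was lost with quantile-normalised FPKM (camera adjusted p = 0.289). HSPA8 rose 1.81-fold and DNAJB1 1.56-fold. HSPA1A and HSPA1B, at 1.99-fold each, are nearly identical copies whose reads the authors' counting could split, so their separate values are uncertain. Both lists kept their call after the length correction, with medians of 0.35 and 0.38.

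Genes of ferroptosis, the iron-dependent form of cell death, moved in both directions. Of 21 tested ferroptosis drivers, 9 rose and 2 fell, the same as when adjusted over the list alone (median 0.17, camera adjusted p = 0.0326; adjusted p = 0.44 with an estimated correlation). PEBP1 and VDAC3 rose by 0.61 ± 0.07 and 0.72 ± 0.09 on the log2 scale (SE), and IREB2, which regulates iron genes, fell by 0.66 ± 0.09. ATF3, the member with the largest rise, is also on the stress and immediate early lists. The drivers' call was lost without saikosaponin A replicate 1 (camera adjusted p = 0.0552), in the 4 libraries of low mitochondrial share (0.0859), on the scale of deposited FPKM (0.116) and with the correction for length and GC content (0.0524). Their median was -0.19 on the TPM scale and -0.01 with library weights. Among 26 ferroptosis suppressors 11 rose and 3 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.143, and 0.00267 without the expression filter). SLC7A11, the suppressor of smallest p, fell by 0.79 ± 0.09 on the log2 scale (SE), a call lost with the length correction. GPX4, which reduces lipid peroxides, rose from 97.5 ± 10.9 to 162 ± 14.7 CPM (SD, n = 3; edgeR adjusted p = 0.00132), and CISD1 rose by 0.43 ± 0.06. GPX4 no longer passed after the length correction (log2 fold change 0.29 ± 0.14, edgeR adjusted p = 0.166). ACSL4 (-0.13 ± 0.08), HMOX1 (0.19 ± 0.10) and TFRC (0.12 ± 0.12) did not pass (log2, SE; edgeR adjusted p = 0.185, 0.159 and 0.44), although TFRC was lower with quantile-normalised FPKM (-0.38, limma adjusted p = 0.0127) and higher in the 4 libraries of low mitochondrial share (0.10, edgeR adjusted p = 0.0153) and after the length correction (0.40, edgeR adjusted p = 0.0491). With the term for that share TFRC passed as higher (0.11, edgeR adjusted p = 0.0029) and ACSL4 as lower (-0.13, edgeR adjusted p = 0.043), and ACSL4 also passed as lower on the scale of deposited FPKM (-0.27, limma adjusted p = 0.03) and among genes with a mean FPKM of at least 5 (-0.25, edgeR adjusted p = 0.0335). Of 26 NRF2 targets 11 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.239, and 0.013 without the expression filter), and SLC6A6 fell by 0.79 ± 0.06.

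Cholesterol synthesis genes rose while fatty acid synthesis genes were split. Of 25 genes of the SREBP2 and cholesterol list, 15 rose and 4 fell, or 17 and 4 adjusted over the list alone (median 0.28, camera adjusted p = 0.0211; adjusted p = 0.44 with an estimated correlation); the median was -0.08 on the TPM scale, and the call was lost on the scale of deposited FPKM (camera adjusted p = 0.0594). The synthesis enzyme genes NSDHL and FDFT1 rose by 0.66 ± 0.06 and 0.61 ± 0.06 on the log2 scale (SE). SREBF2 itself fell by 0.42 ± 0.07, a fall that the length correction reduced to -0.06 (edgeR adjusted p = 0.467). Of 16 fatty acid and triglyceride synthesis genes 4 rose and 5 fell, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.66). FASN, the fatty acid synthase gene, fell from 1464 ± 123 to 637 ± 66.0 CPM (SD, n = 3; edgeR adjusted p = 2.37e-04) and ACACA fell by 0.89 ± 0.06. Both have long transcripts (8565 and 9961 nt). Protein-coding genes of 7543 nt or more had a median log2 fold change of -0.66 and quartiles of -1.02 and -0.30. The fall of ACACA lay between these quartiles, and that of FASN (-1.20) beyond them. Among 6 LXR targets 1 rose (NR1H3) and 1 fell (SREBF1), also when adjusted over the list alone (camera adjusted p = 0.778).

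Genes for ribosomal proteins and for the respiratory chain rose almost without exception. Of 38 cytosolic ribosomal protein genes 37 rose and 0 fell, or 38 and 0 adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 1.69e-11; adjusted p = 0.44 with an estimated correlation). RPL35 rose 2.13-fold, from 264 ± 11.4 to 561 ± 10.5 CPM (SD, n = 3), RPL32 1.92-fold and RPL27 1.89-fold. Ribosomal protein genes have many processed pseudogenes, so their counts depend on how shared reads were assigned. Of 34 nuclear genes of the respiratory chain 32 rose and 0 fell, or 33 and 0 adjusted over the list alone (median 0.58, camera adjusted p = 1.68e-08; adjusted p = 0.44 with an estimated correlation). ATP5MC1 rose 1.95-fold, NDUFB10 1.61-fold, ATP5PO 1.58-fold and COX5A 1.49-fold. Both medians stayed above 0 under each scaling. Both lists hold short transcripts, with medians of 1846 and 2024 nt. After the length correction 25 of the 38 and 16 of the 34 rose, with medians of 0.51 and 0.51 and camera adjusted p = 4.47e-10 and 1.21e-06. Of 15 replication-dependent histone genes 8 rose and 0 fell, also when adjusted over the list alone (median 0.43, camera adjusted p = 0.045; adjusted p = 0.44 with an estimated correlation), H1-2 among them at 1.69-fold and H3C10 at 1.67-fold. Histone genes share reads with their paralogs, and the listed ones have a median length of 869 nt. That call was lost after the length correction (median 0.13, camera adjusted p = 0.783), without DMSO replicate 2 (camera adjusted p = 0.0811), without saikosaponin A replicate 1 (0.0744) and in the 4 libraries of low mitochondrial share (0.0859).

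The log2 fold change fell with transcript length over 10040 protein-coding genes. The Spearman correlation across genes, which are not independent replicates, was -0.72, and the slope was -0.43 per doubling of length. The median ran from 0.64 in the shortest of 10 groups (median length 1205 nt) to -0.66 in the longest (9337 nt). Slopes lay between -0.35 and -0.52 in all 9 pairs of 1 DMSO and 1 saikosaponin A library, and between -0.09 and 0.09 in the 6 pairs within a group. With the length correction 3694 genes changed, 2088 upward and 1606 downward, of which 2732 were also called with the same sign without it and 152 with the opposite sign (124 with length and GC content). FOSB (log2 fold change 5.39 ± 0.23 SE), EGR1 (4.45 ± 0.42), JUN (3.70 ± 0.18) and FOS (3.92 ± 0.18) stayed high, and KMT2D stayed low (-2.16 ± 0.11; edgeR adjusted p = 1.81e-04 for FOSB, FOS, JUN and KMT2D). Besides SLC7A11, DDIT3, GPX4 and SREBF2, the calls of CALR, IREB2, SREBF1, ZMAT3, PTTG1, CDC20, C3, PPARA, MT2A, NDUFB10, COX5A, H1-2, H3C10, OAS3, EGFL7 and SFN were among those lost with the length correction, as was that of ABCC2 (0.07, edgeR adjusted p = 0.371).

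**Figure D2:**
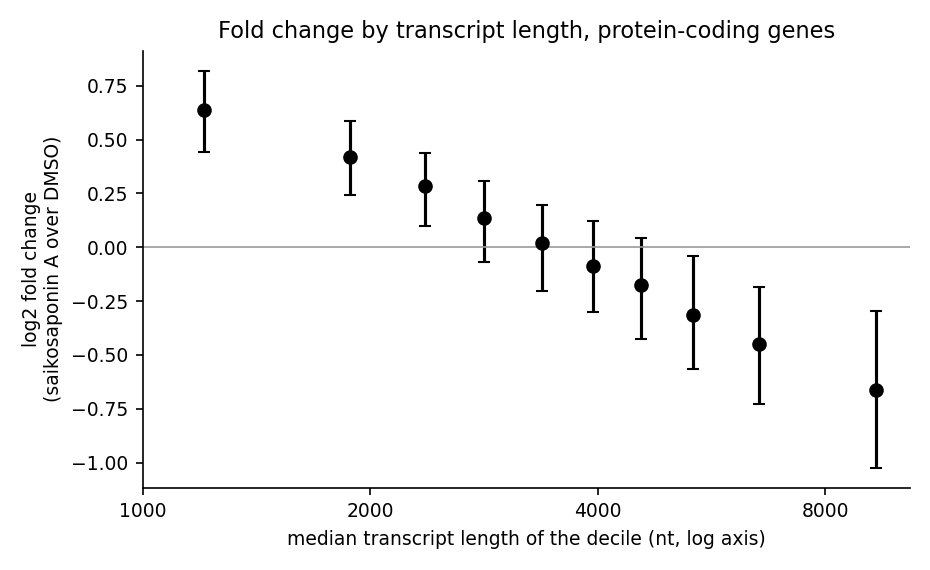
Median log2 fold change (saikosaponin A over DMSO) of protein-coding genes in 10 groups of 1004 genes by transcript length (nt, log axis); bars run from the lower to the upper quartile of genes, not replicate error. The median went from 0.64 in the shortest group to -0.66 in the longest.

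Genes for chromatin regulators and cell junction proteins were prominent among the falls. KMT2D (chromosome 12, 49018978 to 49060794) had a log2 fold change of -3.24 ± 0.14 (SE, edgeR adjusted p = 3.94e-05). SRCAP, a chromatin remodelling gene, fell 11.7-fold but varied, at 146 ± 56.4 CPM in DMSO and 12.6 ± 12.03 with saikosaponin A (SD, n = 3), and overlaps other genes on its strand, among them SNORA30. In replicates 1, 2 and 3 it stood at 111, 116 and 211 CPM in DMSO and at 26.5, 4.91 and 6.48 with saikosaponin A. Single libraries thus move its fold. LTB4R2 fell 7.34-fold and overlaps LTB4R and NOP9 on the same strand, which leaves its value uncertain. Among terms of the deposited annotation, chromatin organization held 136 lower genes where 82.5 would be drawn by chance (Fisher's exact test, adjusted p = 7.35e-10), NSD1 (2.67-fold lower) among them. Cell junction held 203 against 124 (adjusted p = 1.77e-14), with PLEC down 3.86-fold and LRP1 2.97-fold. DNA-binding transcription factor activity held 194 lower genes against 120 (adjusted p = 6.37e-13), although FOS and FOSB, its members with the smallest p, rose. Members of these 3 terms had median transcript lengths of 4109 to 4790 nt, and all 3 remained enriched among lower genes after the length correction (adjusted p from 2.74e-13 to 2.83e-06). Among higher genes, structural constituent of ribosome (139 against 42.6, adjusted p = 1.34e-54) and mitochondrial inner membrane (242 against 105, adjusted p = 4.55e-46) were enriched, with RPS27 up 1.97-fold and COX6A1 up 1.98-fold, and both remained so after the length correction. The response of the kinase GCN2 to amino acid deficiency held 91 higher genes against 29.3 (adjusted p = 3.57e-37), RPL35 among them, while its activator gene GCN1 fell 1.91-fold. RPL35 is also a member of the ribosome term, and the overlap of the terms was not tested. This enrichment is therefore no separate evidence of a GCN2 response. In all, 445 terms were enriched among higher and 375 among lower genes of 4261 tested in each direction, and 154 and 43 after the length correction.

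Targets of YAP/TEAD, the coactivator YAP and the TEAD transcription factors of the Hippo pathway, lay just outside the threshold as a list. Of 22 tested, 3 rose and 11 fell, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.0501), and the list was called without DMSO replicate 1 (camera adjusted p = 0.046), with the term for mitochondrial share (0.0437) and without the expression filter (0.0114). It was not called after the length correction (camera adjusted p = 0.0833), nor without that correction at an estimated correlation (camera adjusted p = 0.44). Its members are long, with a median of 4391.5 nt. ARHGEF17 fell 2.64-fold and AMOTL1 2.10-fold, whereas CCN1 and CCN2, also immediate early genes, rose by 0.85 ± 0.08 and 0.91 ± 0.10 on the log2 scale (SE). Of 16 TGF-beta/SMAD targets 6 rose and 6 fell (camera adjusted p = 0.66), with SKI down 3.07-fold and SMAD6 down 2.37-fold. Of 7 fibroblast and stellate cell genes 0 rose and 3 fell (camera adjusted p = 0.381), COL5A1 and COL1A1 among them at 1.80- and 2.21-fold. The counts of both lists were the same when adjusted over the list alone.

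Hypoxia and glycolysis genes rose, while camera on TMM-scaled counts with the expression filter called no list of the cell cycle, p53, cell death or lysosomes. Of 31 hypoxia and glycolysis genes 15 rose and 1 fell, also when adjusted over the list alone (median 0.31, camera adjusted p = 0.00142; adjusted p = 0.65 with an estimated correlation). The glucose transporter genes SLC2A3 and SLC2A1 rose 2.25-fold and 1.41-fold, P4HA1 1.51-fold and ALDOA 1.48-fold; ALDOA had a log2 fold change of -0.05 with quantile-normalised FPKM. The list kept its call after the length correction (median 0.33) and lost it with quantile-normalised FPKM (camera adjusted p = 0.225) and among genes with a mean FPKM of at least 5 (0.0694). Its median was 0.21 in the 4 libraries of low mitochondrial share and 0.57 between the 2 of high share. Of 29 DNA replication genes 6 rose and 6 fell (camera adjusted p = 0.66), with E2F2 down 1.93-fold and CHAF1A down 1.35-fold; with quantile-normalised FPKM this list was called lower (median -0.18, camera adjusted p = 0.0117). Of 28 G2/M genes 8 rose and 6 fell (0.881), with PTTG1 up 1.58-fold and CDC20 up 1.45-fold. Of 21 p53 targets 9 rose and 4 fell (0.56), FDXR up 1.65-fold and ZMAT3 down 1.63-fold, while CDKN1A did not pass (log2 fold change 0.22 ± 0.12 SE, edgeR adjusted p = 0.152) except without saikosaponin A replicate 3 (edgeR adjusted p = 0.0285). Of 23 BCL2 family and death receptor genes 6 rose and 7 fell (0.66), and the inhibitors of apoptosis XIAP and BIRC3 fell 2.07-fold and 1.67-fold. The counts of these 4 lists were the same when adjusted over the list alone. Of 31 autophagy and lysosome genes 13 rose and 7 fell, or 14 and 7 adjusted over the list alone (0.174, and 0.00879 without the expression filter), with ULK1 down 2.04-fold and NPC2 up 1.74-fold.

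The remaining lists were not called by camera either. Of 13 NF-kB and inflammatory genes 3 rose and 3 fell, or 5 and 4 adjusted over the list alone (adjusted p = 0.66), with CXCL2 up 9.01-fold and BIRC3 down 1.67-fold. Of 13 interferon-stimulated genes 5 rose and 2 fell (0.822), with OAS3 down 1.62-fold and STAT2 down 1.33-fold, and of 5 genes of the metallothionein list 3 rose and 2 fell (0.701), with MT2A up 1.44-fold and MTF1 down 2.41-fold; both counts were the same adjusted over the list alone. Of 30 ribosome biogenesis genes 11 rose and 8 fell, or 12 and 8 adjusted over the list alone (0.66), with POLR1A down 2.37-fold and RRP1B down 1.58-fold. Of 10 genes on the list of nuclear-retained long noncoding RNAs 4 rose and 4 fell, or 5 and 4 adjusted over the list alone (0.701); MALAT1 fell 2.50-fold and the snoRNA host gene SNHG1 rose 1.53-fold. The lists with fewer than 5 tested members had no list test. Of 3 hepatocyte secreted protein genes 1 rose and 1 fell, of 4 genes of hepatocyte transcription factors and metabolism 0 rose and 3 fell, PPARA among them (log2 fold change -1.003), and of 2 endothelial genes EGFL7 rose 1.60-fold. The leukocyte gene CD68 did not pass (edgeR adjusted p = 0.543), and of 3 keratinocyte and epithelial genes KRT17 rose by 0.93 on the log2 scale and SFN 1.44-fold, the latter at -0.0054 (log2) with quantile-normalised FPKM. These counts were also the same adjusted over the list alone.

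**Figure D3:**
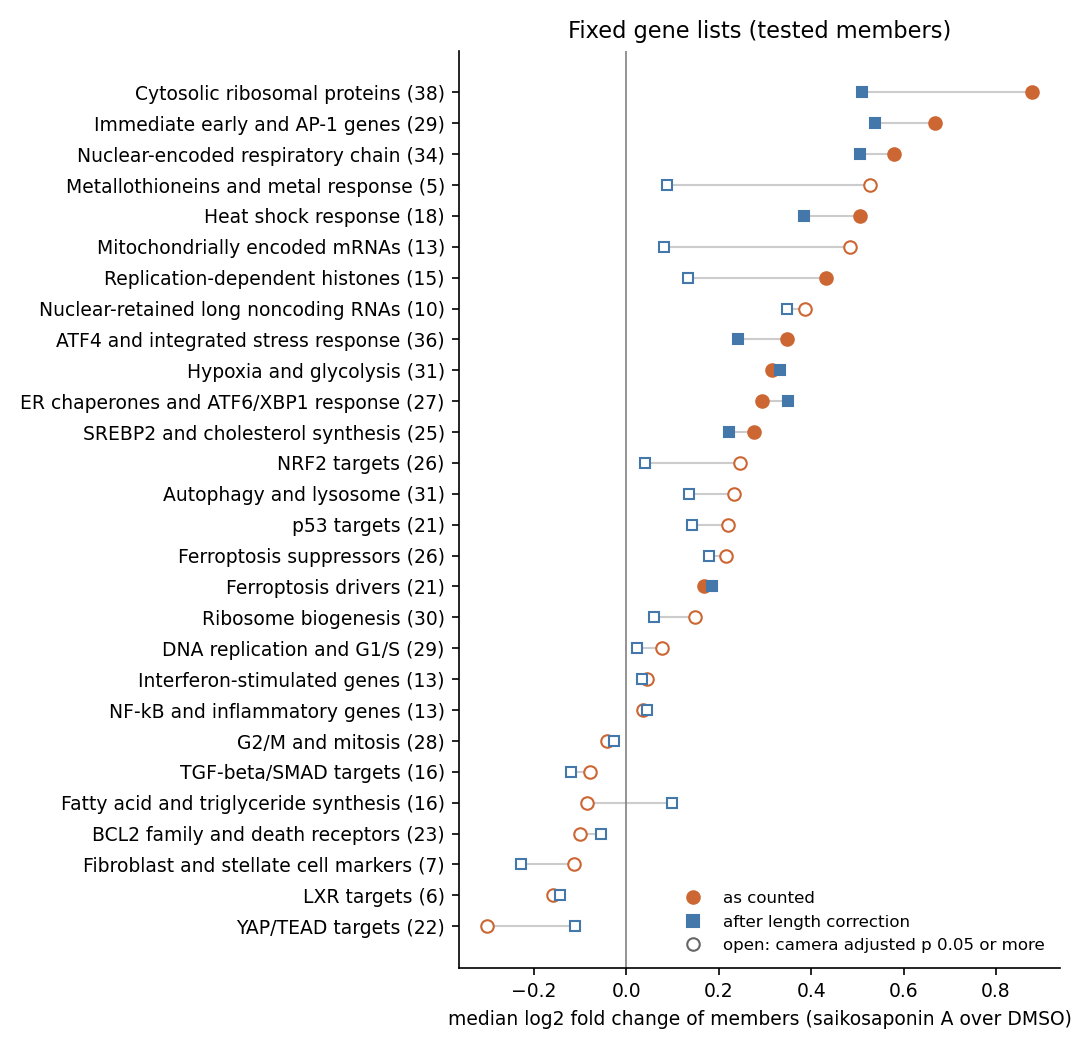
Median log2 fold change (saikosaponin A over DMSO) of the tested members of 28 gene lists, as counted (circles) and after the transcript length correction (squares), with the number of tested members in parentheses; filled symbols mark a camera adjusted p below 0.05. As counted, 10 lists were called, all higher, and 9 of these were also called after the correction.

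Mitochondrial tRNA genes fell while mitochondrial mRNAs did not pass in either direction. Of 22 tRNA genes 17 fell and 1 rose (MT-TS1), with a median log2 fold change of -2.20. MT-TH (mitochondrial genome, 12138 to 12206) fell 11.6-fold, from 15.6 ± 3.88 to 1.34 ± 0.217 CPM (SD, n = 3; edgeR adjusted p = 1.2e-04), MT-TS2 10.4-fold, MT-TL2 9.97-fold, MT-TF 9.86-fold and MT-TY 7.08-fold. The 22 genes took 0.0617 ± 0.0156% of counts in DMSO and 0.0241 ± 0.00668% with saikosaponin A (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 13 mitochondrial mRNAs 0 rose and 0 fell by edgeR, also when adjusted over the list alone, and 3 had an unadjusted p below 0.05, MT-ND5, MT-ND6 and MT-ND3 (list median 0.48, camera adjusted p = 0.66). MT-ND5 and MT-ND6 had log2 fold changes of -1.59 ± 0.61 and -1.43 ± 0.57 (SE, edgeR adjusted p = 0.0606 and 0.0708). Both passed without saikosaponin A replicate 1 (edgeR adjusted p = 0.00696 and 0.00647) and in the 4 libraries of low mitochondrial share (edgeR adjusted p = 2e-08 and 5.32e-08). In those 4 libraries the tRNA median was -2.11.

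**Figure D4:**
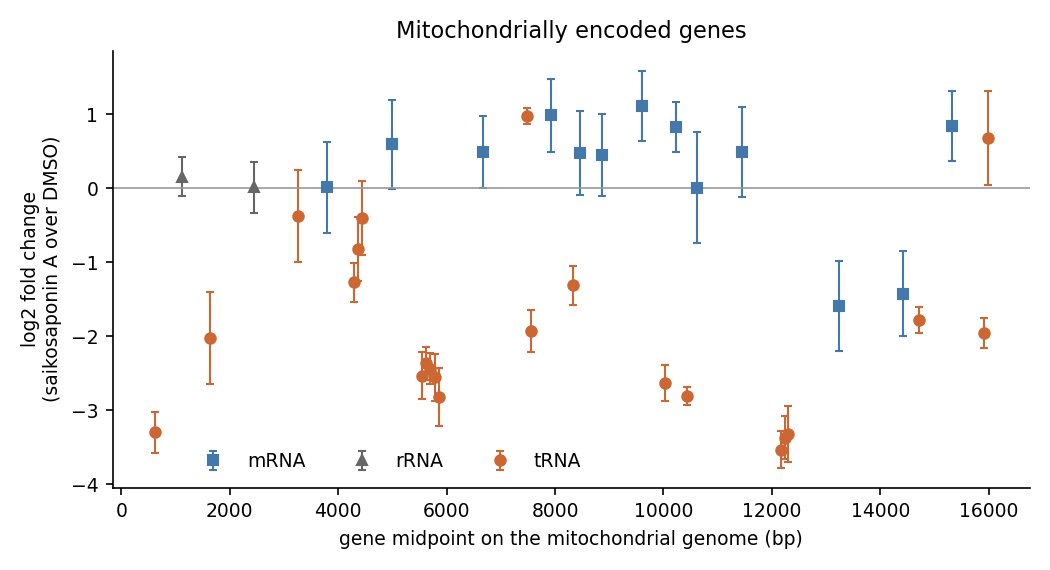
Log2 fold change (saikosaponin A over DMSO) of the 37 mitochondrially encoded genes against their midpoint on the mitochondrial genome (bp), by class; bars are standard errors from edgeR. Of 22 tRNA genes 17 fell, with a median of -2.20, and the median of the 13 mRNAs was 0.48.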

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

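The corrections for transcript length and GC content, the fit to the 4 libraries of low mitochondrial share, the term for that share and the fit without mitochondrial genes were chosen after the data were seen. With 6146 genes changed, 2956 higher and 3190 lower, DESeq2 gave 6757 and its size factors in edgeR 6136. FOSB, EGR1, FOS, JUN and KMT2D kept direction and call in each alternative that tested them. Leaving out 1 library gave 4599 to 6402 changed, 2005 to 3153 higher, 2594 to 3249 lower, 693 to 1120 at least 2-fold, and 8 to 11 lists. With a replicate block 4616 changed, and of the named genes C3 lost its call (edgeR adjusted p = 0.0786). Equal numbers did not always mark like libraries. Across genes, deviations from the group means correlated at -0.34 between the replicates numbered 1, 0.29 between those numbered 2 and -0.35 between those numbered 3. DMSO replicate 3 and saikosaponin A replicate 1 gave 0.55. The block thus joins unlike libraries and is a weak check. The 4 libraries of low mitochondrial share gave 7747 changed, the term for that share 8216 (4173 higher, 4043 lower), and the fit without mitochondrial genes 6141.

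Genes with a mean FPKM of at least 5 are fewer, and 3428 of them changed (1666 higher, 1762 lower, 283 at least 2-fold). There 5 lists were called, without the ER chaperone, ferroptosis driver, cholesterol, hypoxia and histone lists. Without a filter 1361 genes, more of them weakly expressed, changed at least 2-fold, and 13 lists were called, with ferroptosis suppressors, NRF2 targets, autophagy and YAP/TEAD targets added and histones lost. The number higher was 914 with limma on log2(FPKM + 1), 886 and 884 with pseudocounts of 0.1 and 0.01, 923 without a trend and 860 with robust moderation, and the TPM scale gave 49 of 2495 changed. The same limma fit on median-of-ratios scaled FPKM gave 2990 higher and 3149 lower, so the split between directions moved with the scaling of libraries. Library weights gave 5398 lower. At least 2-fold changes numbered 404 on log2(FPKM + 1), 404 without a trend, 403 with robust moderation, 484 with library weights, 359 with median-of-ratios scaling and 301 with quantile normalisation, against 848. They numbered 934 and 1023 with pseudocounts of 0.1 and 0.01 and 1194 on the TPM scale, so on deposited FPKM they rose as the pseudocount fell. For library weights, quantile normalisation and the TPM scale the cause was not tested.

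With the transcript length correction 3694 changed (1606 lower, 421 at least 2-fold), and with length and GC content 3686 (1637 lower, 411 at least 2-fold). Of the genes called with and without the length correction, 152 had opposite signs. Enriched terms numbered 197 with the length correction and 127 among genes changed at least 2-fold, against 820. Against 10 lists called, an estimated correlation gave 0. Quantile-normalised FPKM gave 6, of which 5 were among the 10. The test fry, made without reference to other genes, gave 18: the 10 and the ferroptosis suppressor, NRF2, fatty acid, NF-kB, autophagy, YAP/TEAD, TGF-beta and fibroblast lists.

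With quantile normalisation the DNA replication list had a median of -0.18 (camera adjusted p = 0.0117), and CALR (-0.064), ALDOA (-0.047), HSPA5 (-0.089), SFN (-0.0054) and TFRC (-0.38, limma adjusted p = 0.0127) reversed. ENG reversed with library weights (-0.14, limma adjusted p = 0.0311), and ABCC2 with the length correction (0.066) and with length and GC content (0.021). The cause was not tested. Of 108 named genes 23 kept their direction but lost their call with the length correction, SLC7A11, DDIT3 and GPX4 among them. ABCC2, which reversed, lost its call as well. On the TPM scale 51 lost their call. On simulated counts edgeR recovered 15.8% of 1.5-fold and 68.8% of 2-fold changes among genes below the median count, against 72.4% and 100% above it; this split was chosen after the data were seen.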

Other observations

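The tests of the transcript length trend and of the hepatocyte transcripts, and those of mitochondrial yield and of length for the tRNA genes, were chosen after the result was seen. The test of neighbouring mitochondrial genes and the other splits of the libraries were chosen before.

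Genes abundant in these libraries were picked after their values were seen. The keratin genes KRT18, KRT7 and KRT8 had means of 382 ± 53.4, 308 ± 44.2 and 257 ± 44.5 FPKM in DMSO (SD, n = 3), and the noncoding RNA H19 had 2008 ± 288. The placental alkaline phosphatase gene ALPP stood at 813 ± 40.1, the long noncoding RNA UCA1 at 218 ± 59.5 and the mesenchymal gene VIM at 106 ± 4.15. The epithelial genes CDH1 and EPCAM stood at 0.0511 ± 0.0124 and 0.052 ± 0.0158 FPKM.

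Hepatocyte transcripts such as APOA1, TF and FGB were near the floor in cells labelled HepG2. A loss after saikosaponin A is argued against by the DMSO libraries, where 3 of the 15 secreted-protein genes with a value had a mean of at least 1 FPKM. Too little depth is argued against by 12 of the 15 having an upper 95% limit under 1 CPM in the library of fewest counts, if the counts are reads. Cells other than HepG2 and a derivative of HepG2 that lost these transcripts cannot be told apart, since either gives a low number such as the 3 of 15 seen over all libraries, which restates the pattern. Both stay open.

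Long transcripts such as KMT2D and PLEC fell and short ones such as RPL35 rose. The slope per doubling of length was -0.43 in the 4 libraries of low mitochondrial share, which argues against the 2 libraries of high share as the source, and -0.40 with GC content and gene span in the model, which argues against these as the whole source. A difference in RNA integrity or fragment size between the groups cannot be told apart from an effect of saikosaponin A on long transcripts, because each of the 9 pairs across groups had a slope of -0.347 or below. Gene groups that move with length, such as ribosomal protein and histone genes, may share that source.

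Mitochondrial tRNA genes such as MT-TH and MT-TF fell. A lower yield of all mitochondrial RNA is argued against by their median of -2.64 relative to all mitochondrial counts, and the length trend by their median of -2.20, since the shortest protein-coding genes rose. In the test of neighbouring genes, 18 of 22 lay below the nearest mRNA or rRNA gene by over 1 standard error. That gene was taken regardless of strand, and the standard errors treated genes as independent. For minus-strand genes such as MT-TA and MT-TY, set against plus-strand genes, the test decides little, as the minus-strand mRNA MT-ND6 stood at -1.43. Reads of neighbours are thus argued against only for tRNA genes that lay below a nearest gene on their own strand. MT-TE and MT-TL1 share the strand of their nearest genes, MT-ND6 and MT-RNR2, and did not lie below them by over 1 standard error. Their log2 differences were -0.35 ± 0.60 and -0.39 ± 0.71 (SE), so for them such reads stay possible. The fall was not limited to tRNA genes. Relative to all mitochondrial counts, the mRNAs MT-ND5 (-2.16), MT-ND6 (-2.02) and MT-ND1 (-0.51) were also lower without overlap between groups. MT-CO3 (0.64), MT-CO2 (0.48) and MT-CYB (0.37) were higher without overlap. The median of 0.01 for the 13 mRNAs thus covers shifts in both directions. Poly(A) selection and the size selection of such short RNAs were not tested, nor was whether these reads come from processed tRNAs. Whether saikosaponin A lowers tRNAs or changes the recovery of the RNAs counted here stays open.

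The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with the most genes changed (6146, the highest other 0 by edgeR), at least 2-fold changes (848, the highest other 0), lists called (10, the highest other 8) and terms enriched (820, the highest other 0). The other splits mix both treatments on each side, which widens the spread within sides and leaves part of the treatment difference between them. Their numbers are thus not those of libraries without a treatment difference.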
